A study of Escherichia coli str. K-12 substr. MG1655 with 40 samples.

How the data were processed

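RNA was sequenced from mid-log cultures of Escherichia coli K-12 MG1655 and respiratory variants in M9 minimal medium with 0.2% glycerol or with 2 g/L sodium succinate dibasic, at 37 °C. The libraries were made with the NEBNext Ultra II Directional kit. The 40 libraries form 20 groups of 2 biological replicates. The deposited table, made by the authors, holds TPM for 4216 genes in each library, and its columns sum to between 999897 and 1000000. The processing notes name Bowtie 1.1.2 and DESeq2, while the read counter, the annotation and the gene lengths behind the TPM values are not given in the sources used here. Each column was matched to its sample by strain, medium and replicate number. Of the 4216 genes, 4125 matched the reference table of assembly ASM584v2 by locus tag (4060 protein-coding genes and 65 pseudogenes), and 91 did not match and kept their own identifiers. The table holds 0 rRNA, tRNA or other noncoding RNA genes among those matched.

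Depth was read from the TPM values themselves. Multiplied by gene length plus 1 base, the 600 lowest values of each library are whole multiples of a common step (94% to 96% of them within 0.02), which gives the reads behind each value. The libraries hold 4.23 to 11.28 M reads (median 9.13), the fewest in Suc_eETS-1HA replicate 2 and in Suc_uETS-3HA replicate 2. A value of 3 reads or fewer is treated as the floor. No library is a copy of another.

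Genes with a mean TPM of at least 1 over all libraries were tested (3997 of 4216). limma 3.58.1 in R 4.3.3 was fitted to log2(TPM + 1) with 1 coefficient for each of the 20 groups, empirical Bayes moderation with a mean trend, and Benjamini-Hochberg adjustment over the genes tested. The 20 residual degrees of freedom are shared by all groups, with 5.72 prior degrees of freedom. A gene is called at an adjusted p below 0.05 and a change of at least 1 on the log2 scale. Where several strains are averaged, each strain has the same weight and libraries are the unit, so the p-values refer to these strains. Tables were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

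Within each medium the comparisons are uETS against WT, eETS against uETS, the adapted strain (GlyMOS-A or SMOS-A) against WT, eETS against the adapted strain, 1H and 3H against 2H and 4H, and 1H and 2H against 3H and 4H. WT was compared between the media, the difference in the change from uETS to eETS was tested between the media, and each variant was compared with WT or with its uETS form. The genotypes are not in the labels. That 1H and 2H lack nuoB, 3H and 4H lack ndh, 1H and 3H lack cyoB, and 2H and 4H lack cydB and appC was taken from knowledge of such strains and set against the reads.

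37 gene lists (555 genes, 549 measured) were tested with camera at a preset inter-gene correlation of 0.01, and again with the correlation estimated for each list. Benjamini-Hochberg adjustment ran over the lists of a comparison. Calls of list members were also adjusted over the list alone. Named genes are first the genes taken as missing (nuoB, ndh, cyoB, cydB, appC). Next come the called genes with the largest changes, up to 10 higher and 10 lower. To count, they have to reach 10 TPM in the higher group and move the same way in every strain pair. For the difference between the media the strain pairs were not checked. Last come members of each list that passes or has 3 or more called members. These are up to 4 called members with the smallest p or, where no member is called, the 2 members with the smallest p. Strain means are given for some of these genes whose strains differ. menE as the neighbour of menC and the stretches, prophage and icdC values at the end were picked after their values were seen.

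The comparisons, lists, rule for named genes and most alternatives were fixed before the data were examined. The alternatives were pseudocounts of 0.1 and 5, no filter, a filter at a mean TPM of 10, median-of-ratios scaling, the libraries of 1 medium only, the replicate number as a block, leaving out each library in turn, strains as the unit, and the uETS or eETS strains only. A fit with limma voom on the recovered reads, and a fit without the Gly_uETS-3HA strain, were chosen after seeing the data. The return towards WT was set against 100 simulations with no effect, and with the uETS libraries split by replicate number. With known changes planted in 200 of 3970 genes for simulated data of eETS against uETS on glycerol, 100% of 4-fold and 46% of 2-fold changes were called, with 0 unchanged genes called (by limma voom on 3904 genes 100%, 49% and 1). A planted shift of 13 purine genes gave a camera adjusted p of 8.81e-11 after Benjamini-Hochberg adjustment, and 0 other lists passed. The simulated noise was independent for each gene and library, without differences between strains or correlation between genes. False calls from those sources are therefore not covered. A 2-fold change lies on the limit for a call, which largely sets the share called.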

Results

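The series asks how Escherichia coli carries on growing when parts of its aerobic respiratory chain are taken away, and how expression moves once such variants have adapted to glycerol or succinate. The 40 libraries form 20 groups of 2, which the labels call biological replicates. Each medium holds the wild type (WT), 4 variants named uETS-1HA to uETS-4HA, 4 named eETS-1HA to eETS-4HA, and an adapted strain named GlyMOS-A or SMOS-A. The names are not spelled out in the labels and are read here as unevolved (u) and evolved (e) electron transport variants and as wild type evolved in the same medium. Changes are given as log2 differences ± SE from limma, levels as mean TPM ± SD, and list results from camera with Benjamini-Hochberg adjustment.

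The reads place the missing genes. On glycerol nuoB, a subunit of NADH dehydrogenase I, lay between 0 and 2.42 TPM in the 8 libraries numbered 1H or 2H and between 531 and 1396 TPM in the 8 numbered 3H or 4H, against 763 ± 18.7 TPM in WT (n = 2). The gene of the other NADH dehydrogenase, ndh, showed the opposite layout, at 0 to 0.33 TPM in 3H and 4H and 193 to 573 TPM in 1H and 2H. cyoB, of the proton-pumping cytochrome bo3 oxidase, was at 0 to 3.86 TPM in 1H and 792 to 1714 TPM in 2H and 4H. cydB of cytochrome bd-I and appC of cytochrome bd-II were at 0 to 2.77 TPM and at 0 TPM in 2H and 4H, while cydB reached 1642 to 3112 TPM in 1H and 3H. In Gly_uETS-3HA, cyoB was still read at 64.4 ± 10.3 TPM, against 0.26 ± 0.08 TPM in Gly_eETS-3HA. On succinate the layout was the same, with nuoB at 0 to 7.28 TPM in 1H and 2H, ndh at 0 to 1.09 TPM in 3H and 4H, cyoB at 0 to 1.08 TPM in 1H and 3H, cydB at 0 to 0.19 TPM in 2H and 4H, and appC at 0 TPM there.

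**Figure D1:**
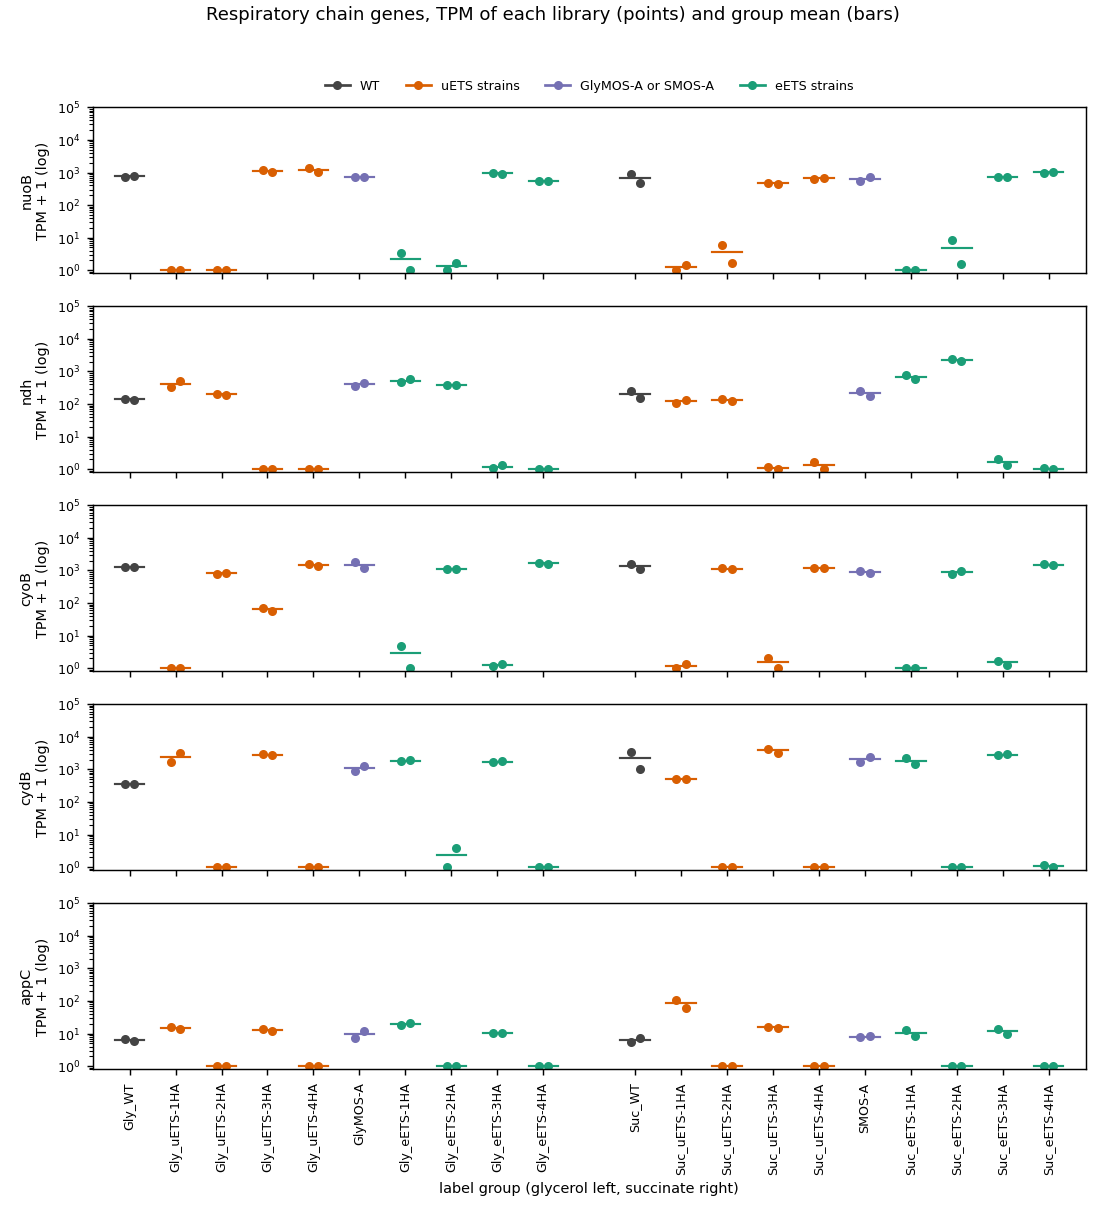
TPM + 1 (log axis) of nuoB, ndh, cyoB, cydB and appC in the 20 groups named on the horizontal axis. Points are the 40 libraries and bars are the means of 2 replicates, for example 64.4 TPM of cyoB in Gly_uETS-3HA.

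In the uETS variants on glycerol, fliC, tar and other motility genes fell against WT, and slp, gadX, dmsA and frdA were among the genes that rose (8 and 2 libraries). fliC, which encodes flagellin, fell by 7.88 ± 0.34 (402 ± 600.4 against 34470 ± 207 TPM; limma, Benjamini-Hochberg adjusted p = 4.5e-16), and the aspartate receptor gene tar fell by 7.28 ± 0.21 (38.5 ± 57.1 against 2276 ± 77.3 TPM). The strains differed in how far this went, since fliC stood at 1368 ± 143 TPM in uETS-3HA, the strain with the cyoB reads above, and at 35.1 ± 2.84 TPM in uETS-4HA. slp, an outer membrane lipoprotein of the acid response, rose by 4.08 ± 0.22 (120.4 ± 24.5 against 6.17 ± 1.86 TPM), and the acid regulator gene gadX by 3.66 ± 0.24. Among genes for respiration with little oxygen, dmsA (dimethyl sulfoxide reductase) rose by 3.76 ± 0.22 (349.9 ± 198 against 17.4 ± 2.42 TPM), frdA (fumarate reductase) by 2.39 ± 0.18, and cydA of cytochrome bd-I by 1.74 ± 0.24 in the mean. In uETS-2HA these genes stood closer to WT or below it, with cydA at 288 ± 0.62 TPM (451 ± 8.03 in WT, 1516 to 3758 in the other 3 variants), frdA at 165 ± 2.02 TPM (117 ± 5.21 in WT) and dmsA at 40.5 ± 2.55 TPM. appB, next to the missing appC, rose by 4.09 ± 0.22 on average, through uETS-2HA and uETS-4HA (401 and 530.5 TPM, against 13.4 and 44.8 TPM in uETS-1HA and uETS-3HA).

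In that comparison 949 of 3997 genes were higher and 199 lower. The median of all genes stood 0.46 above WT, and after scaling to median-of-ratios size factors the counts were 446 and 412. The scaled counts of list members are therefore given in brackets. The flagella and chemotaxis list fell, with 50 of 50 genes lower [50] (camera, Benjamini-Hochberg adjusted p = 1.48e-72, and adjusted p = 0.00674 with an estimated correlation). The acid resistance list rose, with 13 of 14 genes higher [13], among them hdeA (2.28 ± 0.20) and gadB (2.85 ± 0.25) (camera, Benjamini-Hochberg adjusted p = 2.64e-07, and adjusted p = 0.126 with an estimated correlation). Of the anaerobic respiration genes 33 of 42 were higher and 0 lower [22 and 0], with camera adjusted p = 9.68e-07 after Benjamini-Hochberg adjustment and adjusted p = 0.328 with an estimated correlation. The purine synthesis list fell, 11 of 14 genes lower [13], with purF at -1.49 ± 0.33 and purC at -1.99 ± 0.44 (camera, Benjamini-Hochberg adjusted p = 2.75e-07, and adjusted p = 0.286 with an estimated correlation), and so did the ribosomal proteins, 8 of 54 lower [35], with rplB at -1.21 ± 0.28 (camera, Benjamini-Hochberg adjusted p = 1.26e-14, and adjusted p = 0.268 with an estimated correlation). The iron uptake list fell with 7 of 31 genes lower [12], such as the ferrichrome receptor gene fhuA at -1.75 ± 0.19 (camera, Benjamini-Hochberg adjusted p = 1.3e-05, and adjusted p = 0.328 with an estimated correlation). Adjusted over the list alone, these counts are the same. Against WT, the single variants uETS-1HA to uETS-4HA had 1771, 404, 1340 and 1310 genes called, and for uETS-2HA the count was 203 without its replicate 1 and 237 without Gly_WT replicate 2.

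From uETS to eETS on glycerol (8 libraries each), ompC, metE and mqo were among the genes that rose, and glcE, aceA, lamB and glpT among those that fell. ompC rose by 2.48 ± 0.21 (8569 ± 2506 against 1568 ± 596 TPM; limma, Benjamini-Hochberg adjusted p = 3.14e-10), and metE, the cobalamin-independent methionine synthase, by 2.77 ± 0.43 (10280 ± 2182 against 2025 ± 1709 TPM). mqo, malate:quinone oxidoreductase, rose by 2.03 ± 0.11. The glycolate oxidase gene glcE fell by 3.90 ± 0.15, the malate synthase gene glcB by 2.62 ± 0.11 (88.5 ± 25.7 against 819 ± 858 TPM), and aceA, isocitrate lyase, by 2.00 ± 0.13 (1898 ± 581 against 7526 ± 1857 TPM). lamB, the maltoporin, fell by 4.26 ± 0.46 (30.7 ± 17.8 against 641 ± 534 TPM), and glpT and glpF, which carry glycerol 3-phosphate and glycerol, fell by 2.26 ± 0.11 and 1.69 ± 0.11. In Gly_eETS-3HA glpT stood at 2080 ± 19.8 TPM and in Gly_eETS-4HA 224 ± 22.0 TPM.

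Here 146 genes were higher and 300 lower. The list of sugar transport under CRP fell with 18 of 30 genes lower and 1 higher (camera, Benjamini-Hochberg adjusted p = 1.12e-11, and adjusted p = 0.00746 with an estimated correlation), as did glycerol uptake and use with 8 of 13 lower (camera, Benjamini-Hochberg adjusted p = 2.56e-09, and adjusted p = 0.0295 with an estimated correlation). Methionine synthesis rose with 7 of 12 genes higher, such as metK at 1.83 ± 0.13 (camera, Benjamini-Hochberg adjusted p = 2.2e-08, and adjusted p = 0.0295 with an estimated correlation). All 7 genes of the glyoxylate shunt and acetate use list were lower, with actP at -2.44 ± 0.14 (camera, Benjamini-Hochberg adjusted p = 1.13e-08, and adjusted p = 0.0778 with an estimated correlation). Purine synthesis rose with 12 of 14 genes higher, including purF at 1.68 ± 0.21 and guaB at 1.94 ± 0.25, and 36 of 50 flagella genes were lower, including fliA at -2.77 ± 0.26 (camera, Benjamini-Hochberg adjusted p = 9.63e-07 and 6.71e-15, and adjusted p = 0.255 for each with an estimated correlation). The uETS strains differed in motility genes, as for fliC above, so the flagella change is a mean over unlike strains. Of the sulfate and cysteine genes 10 of 15 were higher, with cysK at 1.67 ± 0.21 (camera, Benjamini-Hochberg adjusted p = 0.000232, and adjusted p = 0.345 with an estimated correlation). These counts are the same adjusted over the list alone. With the 8 strains as the unit, paired by number, limma called 0 genes at an adjusted p below 0.05, while 621 of 3997 had an unadjusted p below 0.05, so the values describe these strains. Strain by strain 1185, 629, 568 and 1177 genes were called in 1HA to 4HA, with 712 in 1HA without Gly_uETS-1HA replicate 1 and 318 in 2HA without Gly_eETS-2HA replicate 2.

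GlyMOS-A, read as the adapted wild type, also lost motility expression against WT, and acs, sdhA and glpK were among the genes that fell (2 libraries each). fliC fell by 9.37 ± 0.43 (51.3 ± 4.48 against 34470 ± 207 TPM) and tar by 9.10 ± 0.26. gadX rose by 4.62 ± 0.30 (103 ± 46.3 against 3.04 ± 0.74 TPM; limma, Benjamini-Hochberg adjusted p = 3.02e-12), and ndh by 1.5 ± 0.27 (399 ± 62.3 against 140.2 ± 5.48 TPM). acs, which activates acetate, fell by 2.59 ± 0.25 (172 ± 47.8 against 1024 ± 30.6 TPM), sdhA of succinate dehydrogenase by 1.28 ± 0.21, and the glycerol genes glpF and glpK by 1.94 ± 0.21 and 1.93 ± 0.24. pfkB, the minor phosphofructokinase, rose by 3.22 ± 0.27.

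In GlyMOS-A 574 genes were higher and 203 lower, the median gene stood 0.38 above WT, and the scaled counts were 291 and 298. Without GlyMOS-A replicate 2 the total of 777 became 413. Flagella and chemotaxis fell with 50 of 50 genes lower [50 scaled], and glyoxylate shunt and acetate use with 7 of 7 [7] (camera, Benjamini-Hochberg adjusted p = 1.79e-97 and 2.24e-15, and adjusted p = 0.00253 and 0.00885 with an estimated correlation). The sugar transport under CRP list fell with 12 of 30 genes lower and 2 higher [16 and 1], among them mglB at -2.54 ± 0.32 (camera, Benjamini-Hochberg adjusted p = 3.66e-12, and adjusted p = 0.00343 with an estimated correlation). TCA cycle genes fell, 11 of 16 lower [12], and acid resistance genes rose, 11 of 14 higher [11] (camera, Benjamini-Hochberg adjusted p = 2.2e-12 and 1.45e-08, and adjusted p = 0.0723 and 0.0755 with an estimated correlation). Adjusted over the list alone, the counts are the same except for 13 lower genes in the sugar list.

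The eETS strains on glycerol differed from GlyMOS-A in 91 genes, among them appB, fadB and fliA (8 and 2 libraries). appB rose by 2.94 ± 0.22 (196 ± 205 against 7.97 ± 1.08 TPM; limma, Benjamini-Hochberg adjusted p = 5.74e-10), again through 2HA and 4HA (374 and 384 TPM, against 16.4 and 8.40 TPM in 1HA and 3HA). The fatty acid oxidation gene fadB rose by 2.51 ± 0.45 (151 ± 147 against 13.8 ± 2.90 TPM), with 15.2 ± 0.99 TPM in 1HA and 337 ± 122 TPM in 2HA. mqo rose by 1.44 ± 0.18, and the pyruvate transporter gene btsT by 2.49 ± 0.26. fliA, the flagellar sigma factor, fell by 2.70 ± 0.41. The counts were 54 higher and 37 lower (40 and 46 scaled), and the total of 91 became 180 without GlyMOS-A replicate 2. Acid resistance genes rose, 7 of 14 higher [5 scaled], and 12 of 50 flagella genes were lower, or 17 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.81e-09 and 2.16e-13, and adjusted p = 0.0789 and 0.44 with an estimated correlation). Fatty acid degradation rose with 5 of 9 genes higher, or 6 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.000101, and adjusted p = 0.44 with an estimated correlation). With an estimated correlation 2 other lists kept a camera adjusted p below 0.05.

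**Figure D2:**
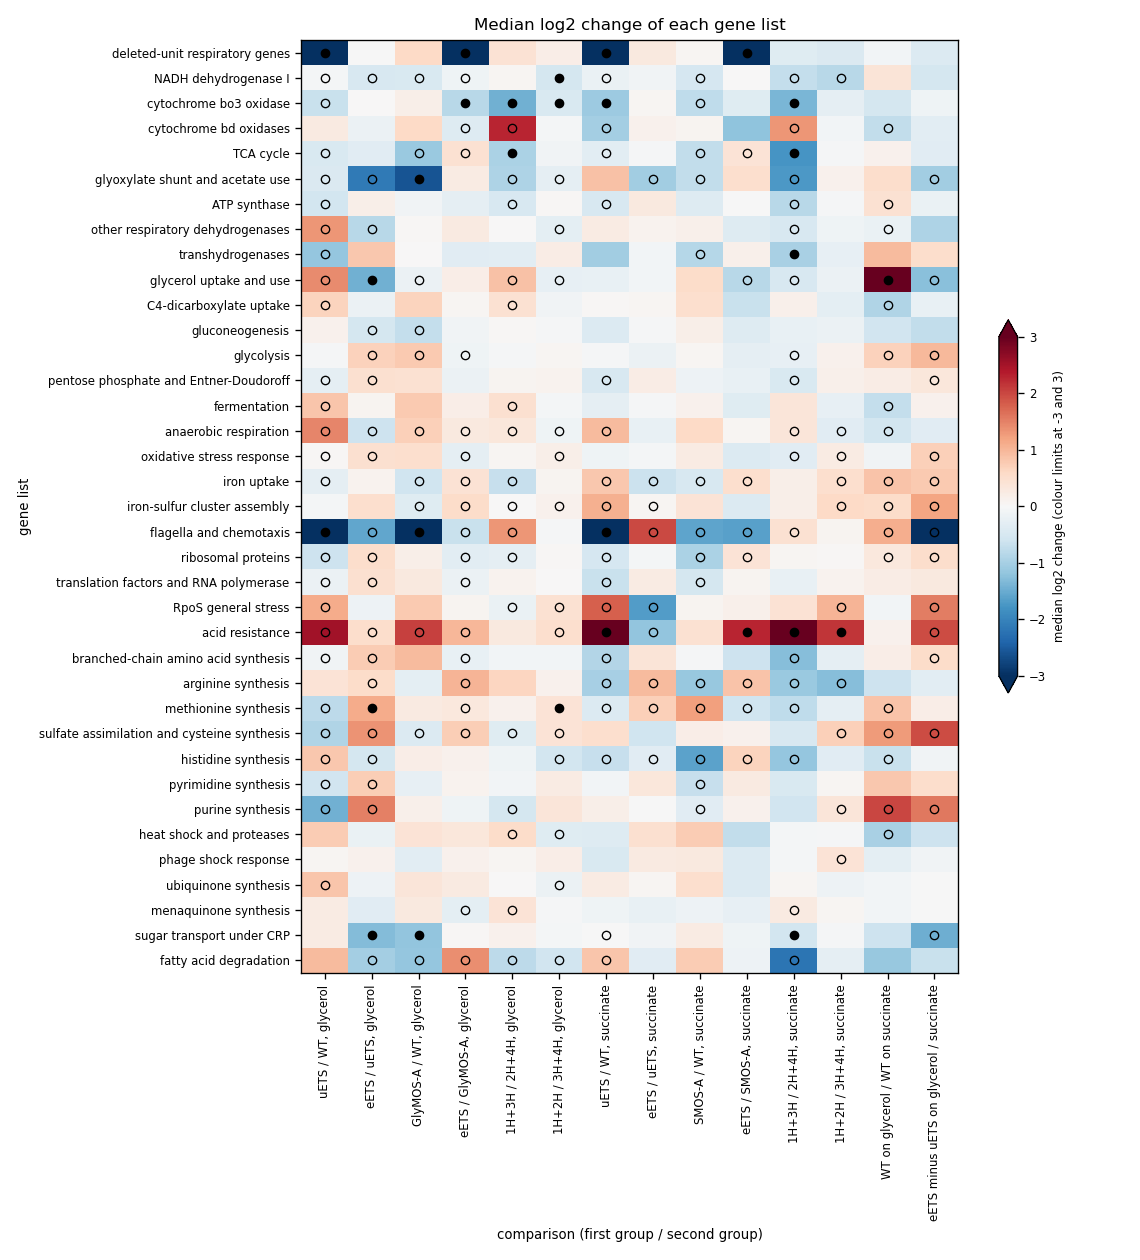
Median log2 change of the 37 gene lists (vertical axis) in the 14 comparisons (horizontal axis), colour running from -3 to 3. Open circles mark lists with a camera adjusted p below 0.05 at the preset correlation of 0.01, and filled circles those also below 0.05 with an estimated correlation.

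Variants that keep cytochrome bd (1H and 3H) and those that keep cytochrome bo3 (2H and 4H) were then compared on glycerol, over uETS and eETS (8 libraries each). menC, which makes o-succinylbenzoate for menaquinone, was higher in 1H and 3H by 4.80 ± 0.10 (146 ± 53.0 against 3.96 ± 0.51 TPM; limma, Benjamini-Hochberg adjusted p = 3.95e-23), and its neighbour menE by 3.81 ± 0.14. arcA, the response regulator of the oxygen-linked Arc system, was higher by 4.32 ± 0.12 (1297 ± 313 against 66.7 ± 28.9 TPM), and cydA by 2.28 ± 0.15 (2870 ± 875 against 741 ± 557 TPM). Higher in 2H and 4H was appB (-4.52 ± 0.14), next to appC, which is missing in these strains. An effect of that deletion on appB was not tested. acs was higher there too (-2.79 ± 0.13; 159.9 ± 91.6 against 1434 ± 1119 TPM). So were the putrescine genes puuA and puuD (-3.46 ± 0.18 and -3.41 ± 0.13) and gltA, citrate synthase (-1.33 ± 0.14). In all, 182 genes were higher and 112 lower in 1H and 3H (147 and 132 scaled). The cytochrome bo3 list fell, with 4 of 5 genes lower, which in part is the missing cyoB itself and its operon (cyoC at 213 to 274 TPM in 1H and 3H, 645 in WT), and TCA cycle genes fell with 6 of 16 lower (camera, Benjamini-Hochberg adjusted p = 1.06e-09 and 1.76e-16, and adjusted p = 0.000431 and 0.0471 with an estimated correlation). The iron uptake list fell with 13 of 31 genes lower, such as cirA at -1.79 ± 0.16, and 38 of 50 flagella genes were higher, with tar at 1.86 ± 0.13, or 0.80 without the Gly_uETS-3HA strain (camera, Benjamini-Hochberg adjusted p = 5.96e-13 and 1.76e-16, and adjusted p = 0.0921 and 0.2 with an estimated correlation). The same counts result adjusted over the list alone. In the uETS strains by themselves 523 genes were called.

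The split by NADH dehydrogenase on glycerol, 1H and 2H (which keep ndh) against 3H and 4H (which keep the nuo genes), gave far fewer genes. Of 3997 genes, 4 were higher and 15 lower (8 libraries each), with nuoB (-9.51 ± 0.27) and ndh (8.41 ± 0.13) the targets themselves. cyoB was lower in 1H and 2H by 1.65 ± 0.20, a value set by the 64.4 TPM in Gly_uETS-3HA, since 1H and 3H otherwise lack cyoB reads, and the difference was 0.14 in the eETS strains by themselves. Where these cyoB reads come from is not settled here. ndh, at 140.2 ± 5.48 TPM in WT, was at 0 TPM in both Gly_uETS-3HA libraries. Methionine synthesis genes rose as a list (median 0.41, and 0.08 in the eETS strains by themselves) with 0 of 12 called, including metN at 0.58 ± 0.10 and metF at 0.76 ± 0.15 (camera, Benjamini-Hochberg adjusted p = 4.65e-07, and adjusted p = 0.0431 with an estimated correlation). Acid resistance genes also rose as a list with 0 of 14 called, and histidine synthesis genes fell with 0 of 8 called (camera, Benjamini-Hochberg adjusted p = 1.29e-07 and 4.93e-10, and adjusted p = 0.0981 and 0.0574 with an estimated correlation), with hdeA at 0.72 ± 0.12 and hisA at -0.58 ± 0.10. Adjusted over the list alone, these counts are the same. The uETS strains by themselves gave 323 calls and the eETS strains by themselves 58.

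On succinate the uETS variants again lost motility expression against WT, and slp, hdeA, gadB and dps were among the genes that rose (8 and 2 libraries). slp rose by 5.88 ± 0.22 (524 ± 436 against 5.91 ± 1.94 TPM; limma, Benjamini-Hochberg adjusted p = 1.32e-17). hdeA, a periplasmic acid chaperone, rose by 5.33 ± 0.20, from 32.9 ± 10.3 TPM in WT to 19550 ± 3990 TPM in uETS-1HA and 318 to 853 TPM in the other 3 variants. gadB, a glutamate decarboxylase, rose by 5.36 ± 0.25, with 6389 ± 2080 TPM in uETS-1HA. dps, which protects DNA in starved cells, rose by 2.36 ± 0.27 (4675 ± 4942 against 606 ± 25.4 TPM). fliC fell by 7.81 ± 0.34 (97.1 ± 32.0 against 26940 ± 24000 TPM) and tar by 7.74 ± 0.21. The glucose dehydrogenase gene gcd rose by 2.27 ± 0.21, and the nitrate reductase gene narJ by 2.60 ± 0.25. cyoD of cytochrome bo3 fell by 1.47 ± 0.15.

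Here 547 genes were higher and 210 lower, the median gene stood 0.19 above WT, and the scaled counts were 414 and 285. The acid resistance list rose with 14 of 14 genes higher [14 scaled], and flagella fell with 50 of 50 lower [50] (camera, Benjamini-Hochberg adjusted p = 8.32e-19 and 1.49e-63, and adjusted p = 0.00547 and 0.00877 with an estimated correlation). The general stress list of RpoS rose with 19 of 20 genes higher [18], among them katE at 2.15 ± 0.27 and otsA at 1.84 ± 0.19 (camera, Benjamini-Hochberg adjusted p = 1.25e-09, and adjusted p = 0.175 with an estimated correlation). Ribosomal proteins fell, 9 of 54 lower [15], with rplB at -1.33 ± 0.28, and branched-chain amino acid synthesis fell, 6 of 13 lower [6], with leuB at -1.50 ± 0.22 (camera, Benjamini-Hochberg adjusted p = 2.8e-06 and 1.21e-05, and adjusted p = 0.45 and 0.244 with an estimated correlation). These counts are the same adjusted over the list alone. Of the anaerobic respiration genes 19 of 42 were higher (camera, Benjamini-Hochberg adjusted p = 0.00279, or 0.407 without Suc_WT replicate 2, and adjusted p = 0.482 with an estimated correlation). The single variants had 1474, 508, 1387 and 892 genes called in the order 1HA to 4HA.

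From uETS to eETS on succinate (8 libraries each), tar and motA were among the genes that rose, and dps, katE and gadB among those that fell. tar rose by 3.01 ± 0.13 (122 ± 179.8 against 5.67 ± 3.03 TPM; limma, Benjamini-Hochberg adjusted p = 5.09e-15), reaching 413 ± 17.1 TPM in eETS-3HA and 13.9 ± 1.54 TPM in eETS-4HA, where WT had 1412 ± 754 TPM. pdeH, a cyclic di-GMP phosphodiesterase of the motility regulon, rose by 3.81 ± 0.18. grcA, a glycyl radical spare part of pyruvate formate lyase, rose by 2.68 ± 0.14 and stood highest in eETS-2HA (32140 ± 1520 TPM, against 3280 ± 363 TPM in uETS-2HA). ndh rose by 1.71 ± 0.13 in the mean, which rests on 1HA and 2HA, since 3HA and 4HA lack it. In 2HA ndh went from 132 ± 10.1 to 2272 ± 243 TPM and in 1HA from 121 ± 17.8 to 680.2 ± 114 TPM, with 204 ± 65.8 TPM in WT. dps fell by 2.69 ± 0.17 (692 ± 639.8 against 4675 ± 4942 TPM), the catalase gene katE by 2.55 ± 0.17, and gadB by 2.52 ± 0.16 (238 ± 432 against 1744 ± 2978 TPM).

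There were 237 genes higher and 233 lower. Flagella and chemotaxis rose with 46 of 50 genes higher, including motA at 2.66 ± 0.20 (camera, Benjamini-Hochberg adjusted p = 1.55e-19, and adjusted p = 0.305 with an estimated correlation). The general stress list of RpoS fell with 18 of 20 genes lower, including osmY at -1.91 ± 0.15, and acid resistance fell with 8 of 14 lower, including hdeA at -1.54 ± 0.12 (camera, Benjamini-Hochberg adjusted p = 6.58e-16 and 8.11e-08, and adjusted p = 0.167 and 0.226 with an estimated correlation). hdeA stayed at 16060 ± 752 TPM in eETS-1HA and came to 110 to 216 TPM in the other 3. Glyoxylate shunt and acetate use fell with 4 of 7 genes lower, including aceK at -1.23 ± 0.10 (camera, Benjamini-Hochberg adjusted p = 1.17e-05, and adjusted p = 0.295 with an estimated correlation). The same counts result adjusted over the list alone. With the 8 strains as the unit, paired by number, limma called 0 genes at an adjusted p below 0.05 (lowest 0.411). An unadjusted p below 0.05 was found for 257 of 3997 genes, not far above the share of 0.05 that arises without an effect. The values therefore describe these strains. Strain by strain 1500, 804, 1822 and 1378 genes were called in 1HA to 4HA.

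**Figure D3:**
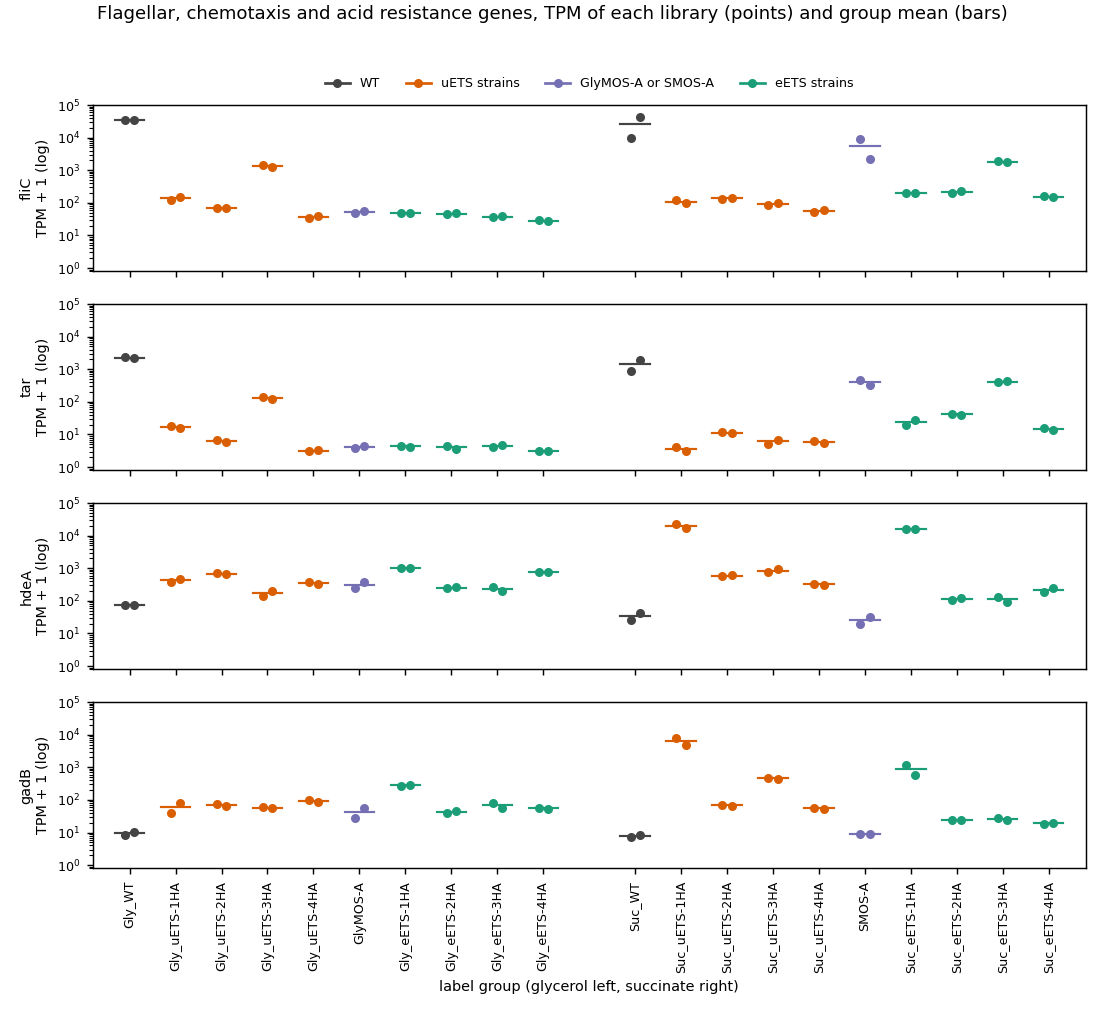
TPM + 1 (log axis) of fliC, tar, hdeA and gadB in the 20 groups named on the horizontal axis. Points are the libraries and bars the means of 2 replicates, for example 19550 TPM of hdeA in Suc_uETS-1HA.

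SMOS-A, read as the wild type adapted to succinate, kept part of its motility expression, with maa, hha and metA among the genes that rose against WT and hisC, hisD and cheA among those that fell (2 libraries each). maa, maltose acetyltransferase, rose by 4.32 ± 0.31 (535 ± 49.9 against 26.1 ± 6.11 TPM; limma, Benjamini-Hochberg adjusted p = 5.42e-10), its neighbour on the chromosome hha, a partner of H-NS, by 4.46 ± 0.41 (858 ± 84.2 against 47.6 ± 40.9 TPM), and the zinc exporter gene zntA by 3.71 ± 0.31. metA, the first step of methionine synthesis, rose by 2.23 ± 0.21 (456 ± 7.03 against 99.8 ± 38.1 TPM), and its regulator metR by 2.26 ± 0.21. The histidine genes hisC and hisD fell by 1.89 ± 0.24 and 1.91 ± 0.25. cheA, the chemotaxis kinase, fell by 2.48 ± 0.27 (221 ± 74.5 against 1274 ± 592 TPM), while fliC fell by 2.22 ± 0.43, or by 1.15 without Suc_WT replicate 2. The fumarate and succinate exchange gene dcuB fell by 2.47 ± 0.29, and fumB, the anaerobic fumarase, by 2.25 ± 0.27.

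In SMOS-A 821 genes were higher and 179 lower, the median gene stood 0.40 above WT, and the scaled counts were 365 and 417. Without SMOS-A replicate 2 the total of 1000 became 653. Ribosomal proteins fell with 26 of 54 lower [42 scaled], with rplD at -1.68 ± 0.29, and histidine synthesis with 8 of 8 lower [8] (camera, Benjamini-Hochberg adjusted p = 2.37e-21 and 1.53e-12, and adjusted p = 0.174 and 0.104 with an estimated correlation). Flagella and chemotaxis fell with 32 of 50 lower [40], or 36 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.49e-24, and adjusted p = 0.174 with an estimated correlation). The other counts adjusted over the list alone are the same.

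Against SMOS-A, the eETS strains on succinate had higher hdeA, hdeB and slp and, in the mean, lower fliC and tar (8 and 2 libraries). hdeA rose by 4.20 ± 0.20 (limma, Benjamini-Hochberg adjusted p = 2.41e-14), from 24.7 ± 8.69 TPM in SMOS-A, with hdeB at 3.98 ± 0.24 and slp at 3.27 ± 0.22. waaL, the O-antigen ligase, rose by 2.62 ± 0.21. fliC fell by 3.76 ± 0.34 (595 ± 754 against 5600 ± 4744 TPM), tar by 2.99 ± 0.21 in the mean, and dmsA by 2.05 ± 0.22. In eETS-3HA fliC came to 1813 ± 116 TPM, with 153 to 218 TPM in the other 3 strains, and tar to 413 ± 17.1 TPM, near that of SMOS-A (398 ± 101 TPM), with 13.9 to 40.6 TPM in the other 3. In all 188 genes were higher and 399 lower, the median gene was at -0.15, and the scaled counts were 275 and 278. The acid resistance list rose with 11 of 14 genes higher [11 scaled] (camera, Benjamini-Hochberg adjusted p = 9.82e-15, and adjusted p = 0.0166 with an estimated correlation). Flagella fell with 30 of 50 lower [28], and ribosomal proteins rose with 8 of 54 higher [11], such as rpsU at 1.79 ± 0.23 (camera, Benjamini-Hochberg adjusted p = 2.65e-11 and 3.98e-07, and adjusted p = 0.685 and 0.704 with an estimated correlation). Adjusted over the list alone, these counts are the same.

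On succinate the oxidase split (1H and 3H against 2H and 4H, 8 libraries each) reached further than menC and arcA. menC was higher in 1H and 3H by 4.48 ± 0.10 (112 ± 57.2 against 3.64 ± 0.76 TPM; limma, Benjamini-Hochberg adjusted p = 1.57e-22) and arcA by 4.44 ± 0.12 (1415 ± 663 against 58.5 ± 17.9 TPM). TCA cycle genes were lower there, with fumA at -2.56 ± 0.09 (362 ± 198 against 1896 ± 259 TPM), gltA at -2.61 ± 0.14, and sdhA at -2.31 ± 0.10. sdhA was lowest in uETS-3HA and eETS-1HA (338 ± 49.3 and 295 ± 67.1 TPM). Fatty acid and acetate genes were lower as well, with fadB at -3.76 ± 0.28 (118 ± 101 against 1320 ± 1061 TPM) and acs at -3.44 ± 0.13 (484 ± 507 against 3498 ± 921 TPM), and so was lldP for lactate uptake (-4.37 ± 0.17). The acid genes gadE and gadA were higher by 4.20 ± 0.16 and 4.06 ± 0.16, mostly through the 1HA strains, where gadE stood at 511 ± 18.7 TPM in uETS and 459 ± 91.5 TPM in eETS, against 106 ± 34.5 and 3.13 ± 0.62 TPM in 3HA and 1.94 to 13.9 TPM in 2HA and 4HA.

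Counts were 274 higher and 268 lower, the median gene was at 0.12, and the scaled counts were 220 and 310. All 16 TCA cycle genes were lower [16 scaled] and 13 of 14 acid resistance genes higher [13], so that the lists fell and rose (camera, Benjamini-Hochberg adjusted p = 7.99e-16 and 1.45e-12, and adjusted p = 0.0296 and 0.0296 with an estimated correlation). Sugar transport under CRP fell with 14 of 30 genes lower [14], such as mglB at -2.35 ± 0.16 (camera, Benjamini-Hochberg adjusted p = 1.47e-06, and adjusted p = 0.0297 with an estimated correlation). Fatty acid degradation fell with 8 of 9 lower [8] and branched-chain amino acid synthesis with 9 of 13 lower [10] (camera, Benjamini-Hochberg adjusted p = 5.43e-07 and 5.43e-07, and adjusted p = 0.163 and 0.116 with an estimated correlation). These counts are the same adjusted over the list alone. The uETS strains by themselves gave 837 calls and the eETS strains 882.

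**Figure D4:**
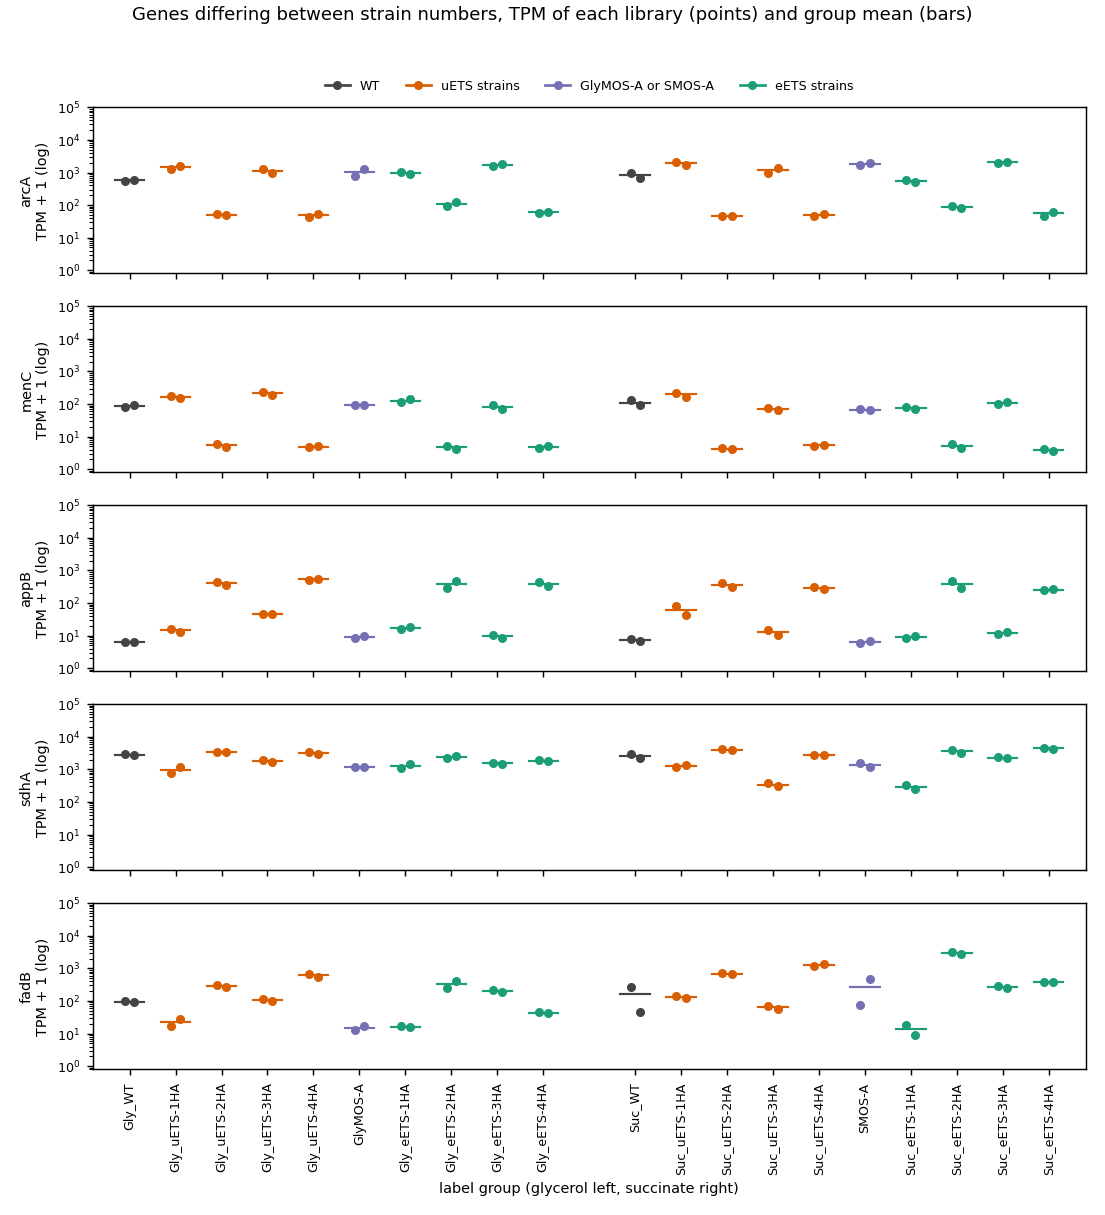
TPM + 1 (log axis) of arcA, menC, appB, sdhA and fadB in the 20 groups named on the horizontal axis. Points are the libraries and bars the means of 2 replicates, for example 46.1 TPM of arcA in Suc_uETS-2HA.

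The NADH dehydrogenase split on succinate (1H and 2H against 3H and 4H, 8 libraries each) gave 101 genes higher and 119 lower (126 and 85 scaled). hdeA was higher in 1H and 2H by 2.90 ± 0.12 (limma, Benjamini-Hochberg adjusted p = 9.55e-16), a mean set by the 1HA strains (19550 ± 3990 TPM in uETS and 16060 ± 752 TPM in eETS). gadE, the activator of the acid genes, was higher by 2.65 ± 0.16, and elaB, of the general stress response, by 1.43 ± 0.14. The hydrogenase 2 gene hybO was at -2.13 ± 0.15 (173 ± 106 against 708 ± 540.1 TPM, and -0.89 in the eETS strains by themselves), and argG of arginine synthesis at -1.52 ± 0.25. The acid resistance list rose with 13 of 14 genes higher [13 scaled] and RpoS general stress with 10 of 20 higher [11] (camera, Benjamini-Hochberg adjusted p = 1.75e-21 and 1.93e-13, and adjusted p = 0.00492 and 0.131 with an estimated correlation). The same counts result adjusted over the list alone. The uETS strains by themselves gave 848 calls and the eETS strains 790.

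WT on glycerol against WT on succinate (2 libraries each) compares expression of the starting strain between the media. It rests on the Suc_WT replicates, which were the least alike of all groups (SD of the log2 difference 0.88). The glycerol 3-phosphate dehydrogenase gene glpD was higher on glycerol by 6.03 ± 0.22 (2548 ± 93.0 against 39.5 ± 15.7 TPM; limma, Benjamini-Hochberg adjusted p = 4.38e-17), and the glycerol kinase gene glpK by 4.73 ± 0.24 (7488 ± 135 against 286 ± 81.4 TPM). purE, an early purine step, was higher by 3.94 ± 0.42. On succinate dcuB was higher (-5.93 ± 0.29), as were the fumarase gene fumB (-4.52 ± 0.27), frdA (-4.19 ± 0.23; 117 ± 5.21 against 2170 ± 395 TPM), dmsA (-3.91 ± 0.28) and cydA (-2.64 ± 0.31). In all 266 genes were higher on glycerol and 430 lower. The glycerol list rose with 12 of 13 higher and 1 lower (camera, Benjamini-Hochberg adjusted p = 6.94e-20, and adjusted p = 0.00155 with an estimated correlation). Purine synthesis rose with 11 of 14 higher, or 12 adjusted over the list alone, and anaerobic respiration fell with 13 of 42 lower and 1 higher, the same count adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 8.61e-07 and 5.78e-06, and adjusted p = 0.506 and 0.517 with an estimated correlation).

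The change from uETS to eETS differed between the media (16 libraries each). By the limma test of the difference, 298 genes had a more positive change on glycerol and 482 a more negative one (387 and 378 scaled, with the median gene at -0.11). The difference was -4.11 ± 0.16 for glpT (limma, Benjamini-Hochberg adjusted p = 1.52e-16), -1.95 ± 0.15 for glcB, 2.45 ± 0.24 for katE and 1.99 ± 0.21 for the enolase gene eno. The flagella list differed, lower on glycerol for 48 of 50 genes [48 scaled], or 49 adjusted over the list alone, and acid resistance was higher for 12 of 14 [12] (camera, Benjamini-Hochberg adjusted p = 7.33e-29 and 2.89e-11, and adjusted p = 0.14 and 0.0613 with an estimated correlation). RpoS general stress was higher for 13 of 20 genes [17], and the sugar transport under CRP list lower for 21 of 30 [18] (camera, Benjamini-Hochberg adjusted p = 2.89e-11 and 8.67e-07, and adjusted p = 0.14 and 0.0613 with an estimated correlation). The other counts adjusted over the list alone are the same. Across 3997 genes the changes on glycerol and succinate had a Pearson correlation of 0.07. Of the called genes 16 were higher in eETS on both media (8.7 for independent lists) and 48 lower on both (17.5), while 52 were lower on glycerol and higher on succinate (17.8) and 11 higher on glycerol and lower on succinate (8.5).

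Calls for uETS against WT were set beside calls for eETS against uETS, which share the uETS libraries, so the numbers for independent lists are given for scale and are not the values without an effect. On glycerol 172 of the 949 genes higher in uETS were lower in eETS (71.2 for independent lists), such as tdcD (2.59 ± 0.33, then -2.54 ± 0.21) and glpB (1.76 ± 0.19, then -1.59 ± 0.12), and 45 of the 199 lower in uETS were higher in eETS (7.3), such as purF (-1.49 ± 0.33, then 1.68 ± 0.21), while 41 of the 199 were lower still in eETS. On succinate 193 of 547 higher genes were lower again (31.9), such as dps and gadB, and 89 of 210 lower genes were higher again (12.5), such as tar. Across genes the Pearson correlation of the 2 changes was -0.24 on glycerol and -0.64 on succinate. In 100 simulations with no effect it was -0.31 and -0.32. Those values follow from the shared uETS libraries and the library numbers alone, so they give no scale for the strength of a return. The simulations held noise only, without differences between strains. The Spearman correlation, which was not simulated, was -0.47 on glycerol and -0.52 on succinate. The covariance was -0.183 and -0.452, against -0.0141 in the simulations of each medium. With the uETS libraries split by replicate number, the correlations were -0.22 and -0.22 on glycerol and -0.62 and -0.61 on succinate. In these splits the 2 changes share no uETS library, but they share the uETS strains.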

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

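The split of the libraries and strains into other groups was planned, and all tests in this part were written before their results were seen. The change from uETS to eETS differed between glycerol and succinate for 780 genes by the limma test of the difference, which is what brings up each gene here. Among the 298 genes with a more positive change on glycerol, the 10 named by the rule are glsA (4.11), gadE (3.33), ycgZ (3.32), ompC (3.15), cysD (3.10), cysP (3.06), dps (2.99), osmY (2.92), hchA (2.88) and cysJ (2.80). The glutaminase gene glsA rose by 1.52 ± 0.19 on glycerol and fell by 2.59 ± 0.19 on succinate. Among the 482 with a more negative change on glycerol, the 10 named are fliA (-5.95), pdeH (-5.69), flgC (-5.47), flgB (-5.17), flgD (-5.10), flgF (-4.99), tar (-4.91), icdC (-4.89), fliN (-4.76) and fliO (-4.71). Agreement between strain pairs was not asked of these named genes. The rise of icdC on succinate comes from eETS-2HA and eETS-4HA (310.8 to 430.1 TPM), with 1.0 TPM or less in eETS-1HA and eETS-3HA. tar fell by 1.90 ± 0.13 on glycerol and rose by 3.01 ± 0.13 on succinate. The fall on glycerol is a mean over uETS strains that differed in motility genes, as seen for fliC. In Gly_uETS-3HA the stretch of neighbouring genes from fliA to dsrB was raised (27 genes, median log2 1.7).

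Other groupings of the libraries bear on these counts, in a plain fit of groups of 8 libraries without strains. These splits part the 2 replicates of a strain, so they say nothing on whether strains chosen anew would part the same way. For the difference between media 1 of 100 splits, the real one, gave 266 genes or more, and the highest other gave 3. The real split keeps the replicates of each strain together, so differences between strains alone can favour it. No split of whole strains was run for this count. For eETS against uETS it was 1 of 100 on glycerol (361 genes, highest other 155) and 1 of 100 on succinate (162, highest other 93). For 1H and 3H against 2H and 4H it was 2 of 100 on glycerol (78, highest other 495) and 1 of 100 on succinate (281, highest other 15). For 1H and 2H against 3H and 4H it was 4 of 100 on glycerol (2 genes, highest other 141) and 4 of 100 on succinate (3, highest other 46). For eETS against uETS, and for 1H and 3H against 2H and 4H on succinate, the real split called the most genes of the 100. Differences between strains can give this as well, so nothing is concluded on the contrast itself. For 1H and 3H against 2H and 4H on glycerol the share is under 0.05 too, but another split called 495 genes, so the count does not single out this contrast, and cyoB, cydB and appC are missing by design along it. For 1H and 2H against 3H and 4H nothing follows, since nuoB and ndh, missing by design along this split, can make up the count of 2 and all but 1 of the count of 3. Splits that call several times the real count, as the 495, 141 and 46, point to a structure of the samples other than the contrast.

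Splits of the 8 strains, 4 against 4, ask whether the strains by themselves part this way. For eETS against uETS 3 of 35 splits gave as many genes on glycerol (446, highest other 582) and 13 of 35 on succinate (470, highest other 735). For 1H and 3H against 2H and 4H it was 7 of 35 on glycerol (294, highest other 582) and 8 of 35 on succinate (542, highest other 735). For 1H and 2H against 3H and 4H it was 35 of 35 on glycerol (19, highest other 582) and 33 of 35 on succinate (220, highest other 735). A chance arrangement of strains cannot be excluded for any of these counts. The split with 582 sets uETS-1HA, uETS-3HA, uETS-4HA and eETS-3HA against the rest on glycerol, and that with 735 sets uETS-1HA, uETS-3HA, uETS-4HA and eETS-1HA against the rest on succinate, which points to differences between single strains.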

How the results depend on the processing

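The fit of limma voom on recovered reads and the fits without the Gly_uETS-3HA strain were chosen after seeing the data, and the other alternatives were planned. Over the alternatives, 632 of 1096 gene results and 62 of 293 list results kept their direction and side of the threshold throughout. Of 32 counts and correlations 20 are taken as unchanged throughout. For a count this means within a factor of 1.5 of the reported one, while the correlations were held to no limit. With the correlation estimated for each list, 209 of 293 list results fell below the threshold, so most list calls rest on the preset correlation. The 84 that stayed on their side include lists that were not called at either correlation. Median-of-ratios scaling took 62 gene results and 18 list results below the threshold and 11 and 5 above it. A filter at a mean TPM of 10 took 25 list results below, and a pseudocount of 5 took 54 gene results below. The replicate numbers do not pair the libraries (median correlation 0 over 45 pairs of groups in each medium), and with them as a block 2 gene results and 3 list results were lost. The count for WT between media went from 696 to 724 with the block, 656 of them shared. When a library is left out its lone partner is assumed to vary like the other groups. Depth limits genes near the floor of 3 reads, above all in Suc_eETS-1HA replicate 2 with 4.23 M reads. Of planted 2-fold changes 46% were called, a share set largely by the limit of 1 on the log2 scale, on which such changes lie.

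The count of 19 for 1H and 2H against 3H and 4H on glycerol moved under several settings. It was 32 and 8 with pseudocounts of 0.1 and 5, 323 in the uETS and 58 in the eETS strains only, 37 without the Gly_uETS-3HA strain and 33 by limma voom. The fits on uETS or eETS strains only average fewer strains. For 1H and 3H against 2H and 4H they gave 523 genes on glycerol (uETS), and 837 (uETS) and 882 (eETS) on succinate, and for 1H and 2H against 3H and 4H on succinate 848 and 790. With strains as the unit limma called 0 genes in eETS against uETS on glycerol and 0 on succinate (621 and 257 at an unadjusted p below 0.05, and the lowest adjusted p was 0.109 and 0.411), a fit with fewer units. uETS-2HA against WT on glycerol had 249 genes with scaling and 254 by limma voom, where the cause was not tested.

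With 1 library left out, the counts ranged from 413 to 1108 (GlyMOS-A against WT), 82 to 180 (eETS against GlyMOS-A), 653 to 1244 (SMOS-A against WT), 203 to 369 (uETS-2HA against WT, glycerol), 712 to 1569 (eETS-1HA against uETS-1HA, glycerol) and 318 to 801 (eETS-2HA against uETS-2HA, glycerol). Some genes reversed in this way, each when a Suc_WT library was left out. Against WT on succinate, argB in uETS ran from -3.22 to 0.10, argI from -2.99 to 0.04 and argH from -2.87 to 0.18. In SMOS-A argF ran from -3.23 to 0.07, ibpA from -0.04 to 5.52, ibpB from 0.00 to 6.35 and hslV from -0.12 to 2.91. Between WT on glycerol and succinate ibpA ran from -5.42 to 0.14. Some lists reversed as well, in their median or in the direction of camera. For eETS against GlyMOS-A they were ribosomal proteins (-0.65 to 0.02) and cysteine synthesis (-0.16 to 1.73), and by the direction of camera alone, with medians above 0, iron uptake (0.18 to 0.51) and arginine (0.12 to 1.81). Others were cysteine synthesis in GlyMOS-A (-1.30 to 0.43), arginine in uETS on succinate (-2.52 to 0.18), flagella (-0.04 to 2.24) and heat shock (-2.50 to 0.39) between WT media, and purine (-1.40 to 0.71) and heat shock (-0.62 to 2.28) in SMOS-A. The lists in comparisons with GlyMOS-A reversed when a GlyMOS-A library was left out, and the rest when a Suc_WT library was. The Suc_WT replicates were the least alike of all groups (SD of the log2 difference 0.88). Why they differ was not tested.

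In the uETS strains only, 1H and 3H against 2H and 4H on succinate reversed for narJ (-0.79), cheR (-0.09), tap (-0.21), metA (0.08) and purC (0.20), and for the lists glycolysis (0.11), anaerobic respiration (-0.75) and flagella (-0.36). In the eETS strains only that contrast reversed for the glycerol list (0.40). 1H and 2H against 3H and 4H in the eETS strains only reversed on glycerol for cyoB (0.14), putA (0.24) and the lists glyoxylate shunt (0.24), other dehydrogenases (0.30), glycerol (0.47), anaerobic respiration (0.62), iron-sulfur assembly (-0.12) and fatty acid degradation (0.26). On succinate it reversed for dcuA (0.53), dcuC (0.92), dmsA (0.11), katE (-0.05), sodA (-0.39), entC (-0.34), fhuF (-0.55), entE (-0.44), guaB (-0.66), anaerobic respiration (0.58) and purine synthesis (-0.90). Without the Gly_uETS-3HA strain nuoB in 1H and 3H against 2H and 4H on glycerol was -1.34, by construction, since fewer strains with nuoB remain in 1 arm.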

Other observations

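The tests of menC, menE and arcA and of icdC and the e14 prophage were chosen after the values were seen, while those of the raised stretches were written before. Single strains carry expression that the means above hide. On succinate eETS-2HA held katG, catalase-peroxidase, at 11120 ± 116 TPM (915 ± 57.5 in uETS-2HA and 944 ± 153 in WT) and ndh at 2272 ± 243 TPM. uETS-1HA on succinate held dps at 12520 ± 2060 TPM and gadB at 6389 ± 2080 TPM, and grcA at 283 ± 83.2 TPM where WT had 4470 ± 2200 TPM. On glycerol uETS-4HA held lldP, the lactate permease, at 754 ± 102 TPM and uETS-1HA at 27.2 ± 6.33 TPM. The flagellar regulator gene flhD was at 209.7 ± 8.20 TPM in WT and 20.5 ± 1.38 TPM in uETS-4HA on glycerol. The most abundant transcript of a library was fliC in Gly_WT (3.46% and 3.43% of TPM) and lpp in Suc_eETS-1HA replicate 2 (10.32%). The replicates of Suc_WT and Gly_uETS-1HA differed most (SD of the log2 difference 0.88 and 0.79).

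Neighbouring genes were raised together in the evolved succinate strains, on the side of the replication origin in eETS-2HA, eETS-3HA and eETS-4HA and mainly in another stretch in eETS-1HA (0.46 in eETS-2HA and 0.32 in eETS-3HA over that stretch). With a window of 31 genes and a limit of 0.6, both picked after looking, the longest stretch was 97 genes from yibL to recF in eETS-4HA (median log2 0.93), 85 from yibQ to recF in eETS-2HA (1.07), 65 from uspB to glyQ in eETS-1HA (0.92) and 62 from dfp to dnaA in eETS-3HA (1.11). Shorter ones were 3 in eETS-3HA, from insI3 to fimG (39 genes, 1.00), glyS to yibI (37, 1.2) and kduD to uacT (33, 1.17), and 1 each in eETS-2HA, ysaA to trmL (32, 0.81), and eETS-1HA, rimJ to fabH (25, 1.15), while in groups other than the succinate eETS strains the longest was 42 genes (Suc_uETS-3HA). Over the longest stretches of eETS-2HA, eETS-3HA and eETS-4HA the medians were 0.46, 0.45 and 0.42 in SMOS-A and -0.25, -0.26 and -0.25 in eETS-1HA, and 0.05 or lower in the groups other than SMOS-A and the succinate eETS strains. A dosage gradient around the origin would raise the far side too, but its median was at most 0.09 of that of the stretch, which argues against it, while a gain in copies may explain the pattern and stays open, since the spread of change inside the stretch was up to 1.43 times that outside (eETS-1HA) and 0.81 to 0.84 times in the others, and no DNA reads are used here.

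The 2H and 4H strains lack nearly all menC, menE and arcA transcript before and after evolution. menC lay at 2.59 to 4.93 TPM in their 16 libraries and 63.2 to 229 TPM in the 24 others, menE at 0.80 to 3.50 and 20.0 to 79.4 TPM, and arcA at 42.9 to 127 and 528 to 2152 TPM. A change of the whole men operon is argued against by menB, upstream of menC, whose mean differed by a factor of 1.35 at most. Less repression by ArcA in 2H and 4H may be part of the difference in other genes. The 13 genes listed as ArcA-repressed had medians of -0.88 on glycerol and -1.84 on succinate (6 and 10 called lower in 1H and 3H, 0 higher). They are mainly lld, glc and bet genes, neighbours on the chromosome, so the counts are not of independent genes. The limit set for the medians was met on succinate and missed on glycerol, so the test does not decide. An effect of the remaining oxidase was not tested. A lesion of the parent strain and an effect of the missing oxidase cannot be told apart for menC (highest value 4.93 TPM), since the labels give no parentage and no strains other than 2H and 4H lack these oxidase genes.

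In the evolved succinate strains eETS-2HA and eETS-4HA icdC, a remnant copy of the end of icd at the far border of the e14 prophage, had 450 to 650 reads in 4 libraries, against 14 at most in the other 36. The 23 genes of e14 kept 0.2% of their uETS reads in eETS-2HA and 37.7% in eETS-4HA, where the other 36 libraries have 426 to 2363 reads. In the other 36 libraries icd reads are not assigned to icdC in such numbers, since the highest icdC count there is 3.11% of the lowest of the 4. Those libraries keep their e14 reads, so whether icd reads fall on icdC where e14 is lost was not tested. Loss of the prophage from all of the eETS-2HA culture and part of the eETS-4HA culture may explain both values, as the 20 flanking genes moved by a median of -0.12 and -0.37 and do not share the loss. No biological consequence of it was tested.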
